A study of Homo sapiens with 6 samples.

How the data were processed

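The series holds 6 RNA sequencing libraries from human trophoblast stem cells differentiated for 8 days, 3 with shRNA against CITED2 and 3 with a control shRNA. Groups and replicate numbers came from the sample titles. The cell line and the meaning of the shRNA names are not given in the sources used here. Per the labels' protocols, total RNA was made into libraries with a TruSeq RNA kit and sequenced as 100-bp paired-end reads, and the authors mapped the reads to GRCh37 with CLC Genomics Workbench 20.0.4. The annotation release, the handling of reads that map to several places and the use of strand in counting are not given in the sources used here.

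The deposited table has 57773 genes. It holds raw counts per gene and sample, deposited as total exon reads, unique exon reads and total intron reads per the file headers. It also holds RPKM, which the authors gave as reads scaled to exon length and mapped reads and which equalled total exon reads divided by exon length and a constant for each sample. The deposited comparison of the authors gives a fold change, a p-value and a false-discovery-rate p-value from an EDGE test with tagwise dispersions, per the file headers. Their cut-off per the labels was a false-discovery-rate p-value of 0.05. XIST, TSIX and the Y chromosome (497 genes) were left out of every step, which left 57276 genes. Gene starts in the table count from 0, since 35899 of 36297 genes with the annotated end started 1 bp before the annotated start, and were shifted by 1. Biotype, strand and overlapping genes came from GENCODE release 44 mapped to GRCh37, in which 96.1% of the identifiers were found.

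Total exon reads ranged from 25174001 to 29646622 per library, of which 86.4% to 88.8% were unique. No pair of libraries differed by as little as sampling noise, with a chi-square per degree of freedom of at least 62.4 over genes, so no 2 of them were merged as repeat counts of 1 library. This does not show that they came from separate cultures, and each library counted as 1 replicate by its label. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on total exon reads with TMM scaling and the default filterByExpr, which kept 14248 genes. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were computed as the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. DESeq2 1.42.0 gave adjusted p-values as NA for 20 genes, which stayed NA. The common biological coefficient of variation was 0.378.

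Before the data were examined, 23 gene lists (458 entries, 457 of them matched by symbol or older symbol, PECAM1 not) were fixed for extravillous, stem cell and cytotrophoblast, syncytiotrophoblast, amnion-type, stromal and immune markers, cell cycle, hypoxia, CITED family and partners, proteases, matrix and integrins, mesenchymal, epithelial, interferon, NF-kB, p53, stress response, cholesterol, TGF-beta, Notch and WNT, angiogenic, imprinted and mitochondrially encoded genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation and with fry. No list passed with the estimated correlation or in the directional test of fry. Bootstrap intervals of list medians used 2000 draws of members. Values per library are medians over members of log2 CPM, with a prior count of 2, minus the control mean.

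The rule for named genes, also fixed in advance, took CITED2, the 10 largest folds in each direction among adjusted p under 0.05 with non-overlapping groups and at least 5 CPM in the higher group, and the 3 smallest p-values of each list. The second part gave 0 genes in the edgeR fit, so it was applied to the DESeq2 calls after the data were seen, where 527 genes met it. Genes with under 50% unique reads were called uncertain, and so was CSH1 because of its near-identical copies. Other named genes lay above 50% with part of their reads not unique. Among them were IGF2 (59.1% unique), PDGFRA (60.3%), CNTNAP1 (65.2%), HSD17B1 (65.5%) and C19orf33 (66.6%).

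The steps were tested on simulated counts with the real means, library sizes and dispersions of the knockdown and control comparison over 14248 genes. The simulation left most genes unchanged, drew each gene independently and held no differences shared across genes within a library. Its shares therefore need not hold for the real counts. The edgeR quasi-likelihood test called 4.48%, 61.2% and 93.9% of genes changed by 2, 4 and 8 times, and 10.7% of its calls were unchanged genes. DESeq2 called 22.4%, 80.6% and 97.0%, and 28.1% of its calls were unchanged genes. The edgeR exact test called 13.4%, 77.6% and 98.5%, and 23.1% of its calls were unchanged genes.

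The alternatives fixed in advance were RLE factors, library size alone, no filter, DESeq2, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1), unique exon reads, a replicate block, each of the 6 libraries left out, and stricter thresholds. The edgeR exact test, edgeR's legacy quasi-likelihood test and DESeq2 with each library left out were added after seeing the data. The median log2 fold change of all genes moved by 0.06 with library size alone. Intron reads were tested with the same edgeR fit.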

Results

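Gene expression was measured by RNA sequencing in human trophoblast stem cells, the self-renewing precursors of the placental epithelium, after lentiviral delivery of short hairpin RNA (shRNA), puromycin selection and 8 days of differentiation toward extravillous trophoblast, the invasive cell type that enters the uterine wall. The 6 libraries fell into 2 groups of 3. In the knockdown group the shRNA targeted CITED2, a transcriptional co-regulator that binds CBP and p300, and the control group received the shRNA labelled scr. The counts held 28200323, 25174001 and 27469371 exon reads in control replicates 1, 2 and 3, and 25489320, 29646622 and 27854689 in knockdown replicates 1, 2 and 3. The labels did not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples. The comparison asked which genes depended on CITED2 in cells directed toward extravillous trophoblast.

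CITED2 itself (ENSG00000164442, chromosome 6, positions 139693393 to 139695757 of GRCh37, minus strand, protein-coding) had 534, 560 and 214 CPM (counts scaled to library size) in control replicates 1, 2 and 3 and 88.3, 86.1 and 81.5 CPM in the knockdown replicates. Its mean was 436 ± 193 CPM (SD, n = 3) in the controls and 85.3 ± 3.45 CPM (SD, n = 3) in the knockdown. The log2 fold change of knockdown over control was -2.35 ± 0.37 (SE), a level of 19.6% of control. All 3 knockdown libraries lay below all 3 controls, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. The decrease did not pass in the quasi-likelihood test of edgeR (adjusted p = 0.081) and passed in DESeq2 (adjusted p = 3.08e-06). Without control replicate 3, the control with the lowest CITED2 level, the edgeR quasi-likelihood test gave a log2 fold change of -2.68 and an adjusted p of 0.0152.

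**Figure D1:**
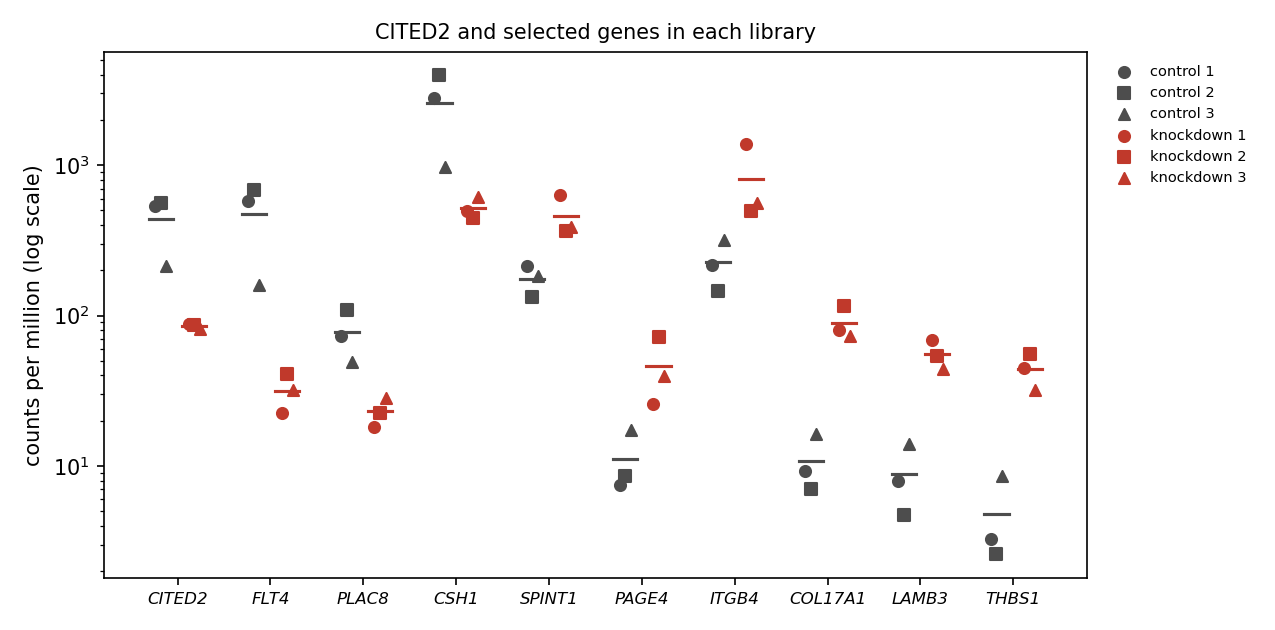
CPM on a log axis for CITED2 and 9 other genes in each of the 6 libraries, with control libraries in grey, knockdown libraries in red, marker shapes for replicates 1 to 3 and a horizontal line at each group mean. CITED2 lay between 81.5 and 88.3 CPM in the knockdown libraries and between 214 and 560 CPM in the controls, and control replicate 3 was the control nearest to the knockdown libraries for CITED2 and FLT4.

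The largest differences among named genes included a loss of the lymphatic growth factor receptor gene FLT4 and of the parathyroid hormone receptor gene PTH1R, and a gain of the junctional protein gene JPH2, the receptor tyrosine kinase gene AXL and the metallothionein gene MT2A. Over 14248 tested genes, the edgeR quasi-likelihood test called 0 genes at an adjusted p under 0.05, with a lowest adjusted p of 0.081 shared by 39 genes. At an unadjusted p under 0.05 it counted 2065 genes, of which 1189 were higher and 876 lower in the knockdown. DESeq2 called 749 genes, 450 higher and 299 lower, a balance that turned to 387 higher and 476 lower without knockdown replicate 1. The edgeR exact test called 644 genes, 386 higher and 258 lower. Limma-trend on log2(RPKM + 1) called 0. In 2941 genes, 20.6% of those tested, the 3 libraries of one group lay entirely above those of the other, where chance gives 10% on average over splits. Genes move together, so a single split can lie far from 10% without an effect of the knockdown. Leaving out control replicate 3 raised the edgeR quasi-likelihood count from 0 to 107 genes, and leaving out any other library left it at 0. The DESeq2 count was 256 without control replicate 1, 248 without control replicate 2 and 454 without knockdown replicate 3, and 183 genes were called by DESeq2 with all 6 libraries and without each library in turn.

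Since no gene passed in edgeR's quasi-likelihood test, the genes with the largest folds were taken from the DESeq2 calls, a choice made after the data were seen. Among the genes lower in the knockdown, FLT4 (ENSG00000037280, chromosome 5, positions 180028506 to 180076624) fell from 474 ± 277 CPM to 31.7 ± 9.07 CPM (SD, n = 3 each), a log2 fold change of -3.90 ± 0.55 (SE; DESeq2 adjusted p = 6.68e-11). PTH1R fell from 24.4 ± 16.8 to 0.966 ± 0.376 CPM (SD, n = 3 each; DESeq2 adjusted p = 4.38e-10). DPPA3, a gene of the germ line and early embryo, had 6.52 ± 5.78 CPM in the controls and 0.174 ± 0.108 CPM in the knockdown (DESeq2 adjusted p = 4.77e-07). The log2 fold change of DPPA3 went from -5.25 to -4.32 without control replicate 2. The aminopeptidase gene listed as AQPEP fell by 3.12 ± 0.39 (SE) on the log2 scale (DESeq2 adjusted p = 5.29e-11). CNTNAP3, SLN and PGM2L1 had log2 fold changes of -3.34, -3.13 (-3.83 without knockdown replicate 1) and -2.91. EGFR-AS1, HCAR3 and GPR146 also met the rule, with log2 fold changes of -5.10, -3.11 and -2.95, but only 13.2%, 0% and 6.97% of their reads were placed uniquely. EGFR-AS1 lies antisense inside EGFR, HCAR3 has a near-identical paralog and GPR146 lies within C7orf50, so their own levels are uncertain. Without control replicate 2 the log2 fold changes of EGFR-AS1, HCAR3 and GPR146 were -4.32, -2.48 and -2.29.

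Among the genes higher in the knockdown, LAMP3, which encodes a lysosomal membrane protein, rose from 2.17 ± 1.22 to 22.7 ± 4.65 CPM (SD, n = 3 each), a log2 fold change of 3.38 ± 0.44 (SE; DESeq2 adjusted p = 6.68e-11). JPH2 rose from 2.64 ± 0.844 to 30.5 ± 19.2 CPM (SD, n = 3 each; DESeq2 adjusted p = 4e-09). The JPH2 log2 fold change went from 3.52 to 2.89 without knockdown replicate 1. AXL rose from 0.859 ± 0.877 to 9.42 ± 5.59 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.000117). The AXL log2 fold change went from 3.42 to 4.71 without control replicate 3 and to 2.86 without knockdown replicate 2. The laminin gene LAMB4, C19orf33 and MYO16 had log2 fold changes of 3.73, 3.63 and 4.02, and of 5.68, 5.54 and 7.29 without control replicate 3. MYO16 had 3.35 without knockdown replicate 2. CNTNAP1 had 19.1 CPM in knockdown replicate 1 and 4.07 and 2.67 CPM in knockdown replicates 2 and 3, and its log2 fold change went from 3.45 to 2.10 without that replicate and to 4.35 without control replicate 3. Knockdown replicate 1 carried much of the gain of MT2A, with 464 CPM against 57.8 and 77.1 CPM in knockdown replicates 2 and 3 and 15.0 ± 4.35 CPM (SD, n = 3) in the controls. The log2 fold change of MT2A was 3.73 with all libraries and 2.17 without knockdown replicate 1. The myosin gene MYH14 had 742 CPM in knockdown replicate 1 and 133 and 98.8 CPM in knockdown replicates 2 and 3, and its log2 fold change went from 3.37 to 1.89 without that replicate. ADORA2A, with a log2 fold change of 4.55 (5.51 without control replicate 1, 3.75 without knockdown replicate 1), shares its position with a read-through gene and an antisense gene, and 4.25% of its reads were unique. DESeq2 called 16 of these 20 genes also without each library in turn, with SLN, HCAR3, ADORA2A and MYO16 as the exceptions.

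The list of extravillous trophoblast markers was lower in the knockdown by camera with the preset correlation (adjusted p = 8.17e-15) and not with an estimated correlation (adjusted p = 0.295). The list of trophoblast stem cell and cytotrophoblast markers was higher with the preset correlation (camera adjusted p = 1.34e-08) and not with an estimated correlation (adjusted p = 0.295). Of 27 measured extravillous markers, 24 had a negative log2 fold change, and the median was -1.33 (95% bootstrap interval -1.66 to -1.02). None passed in edgeR's quasi-likelihood test adjusted over all genes tested, 15 were lower and 1 higher when adjusted over the list alone, 11 did not pass, and DESeq2 called 12, all lower. FLT4 led the list. PLAC8 fell from 77.2 ± 29.6 to 23.1 ± 5.05 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.000435). The fibronectin gene FN1 had a log2 fold change of -1.75 ± 0.53 (SE), and HLA-G, the class I molecule typical of these cells, had -1.57 ± 0.45 (SE), with DESeq2 adjusted p-values of 0.00814 and 0.0109, and both calls were lost without control replicate 1 or without control replicate 2. CSH1, a placental lactogen gene whose reads are 68.5% unique because of near-identical copies, had a log2 fold change of -2.31 and remains uncertain. AOC1 (1.38 ± 0.52, SE) was the member that was higher over the list alone, and DESeq2 did not call it (adjusted p = 0.126). It had 2.83, 2.05 and 1.58 CPM in control replicates 1 to 3. In knockdown replicate 1 it had 2.17 CPM, within the control range, and in knockdown replicates 2 and 3 it had 7.73 and 6.85 CPM. The median over the list, relative to the control mean, was 0.34, 0.22 and -0.45 in control replicates 1 to 3 and -1.38, -1.20 and -1.05 in the knockdown replicates.

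Of 22 measured stem cell and cytotrophoblast markers, 21 had a positive log2 fold change, with a median of 1.08 (95% bootstrap interval 0.61 to 1.83). Over all genes tested 0 passed in edgeR's quasi-likelihood test, adjusted over the list alone 8 were higher and 0 lower with 14 not passing, and DESeq2 called 6, all higher. PAGE4 rose from 11.1 ± 5.38 to 45.9 ± 23.8 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.00113), and the protease inhibitor gene SPINT1 rose from 176 ± 40.8 to 462 ± 150 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.005). The integrin gene ITGB4 and TEAD4, a transcription factor gene of the stem cell state, had log2 fold changes of 1.84 ± 0.47 and 2.13 ± 0.58 (SE), with DESeq2 adjusted p-values of 0.00594 and 0.00752. Knockdown replicate 1 carried much of both, with 1376 CPM of ITGB4 against 499 and 560.1 CPM and 50.5 CPM of TEAD4 against 11.8 and 12.5 CPM in knockdown replicates 2 and 3. Without it the log2 fold changes were 1.22 and 1.09. DESeq2 called neither without control replicate 1 or without control replicate 2, and did not call SPINT1 without control replicate 2. TP63 and ELF5 had log2 fold changes of 1.02 ± 0.48 and 0.67 ± 0.57 (SE) and did not pass in either tool.

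The syncytiotrophoblast markers, those of the hormone-producing fused layer, did not move as a list. Of 29 measured members, 20 had a positive and 9 a negative log2 fold change, the median was 0.26, and camera gave an adjusted p of 0.784, or 0.952 with an estimated correlation. Adjusted over the list alone, 2 members were lower, 0 higher and 27 did not pass, and 0 passed over all genes tested. The leptin gene LEP fell from 5294 ± 2186 to 1268 ± 569 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.00093), and HSD17B1, an estrogen-synthesising enzyme gene, rose from 447 ± 268 to 1169 ± 156 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.0453), a call lost in 4 of the 6 DESeq2 fits with 1 library left out. CSH2, which shares reads with CSH1, had a log2 fold change of -2.42. Without knockdown replicate 1 the list was higher in the knockdown (median 0.57, camera adjusted p = 0.00227), and without knockdown replicate 3 its median was -0.07. The amnion-type epithelial markers did not pass either. Their 7 measured members had a median of 1.0 (camera adjusted p = 0.102, or 0.435 with an estimated correlation), and WNT6, with 7.64 ± 7.89 CPM in the controls and 58.3 ± 29.3 CPM in the knockdown (SD, n = 3 each), was the 1 member higher over the list alone. The log2 fold change of WNT6 was 2.92, or 4.21 without control replicate 3, and DESeq2 did not call it without knockdown replicate 1 (adjusted p = 0.209). The amnion-type median went to 0.16 without knockdown replicate 2, to 1.72 without control replicate 3, when camera passed (adjusted p = 0.0106), and to -0.08 without the filter on low counts. Camera also passed without knockdown replicate 1 (adjusted p = 0.0254).

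**Figure D2:**
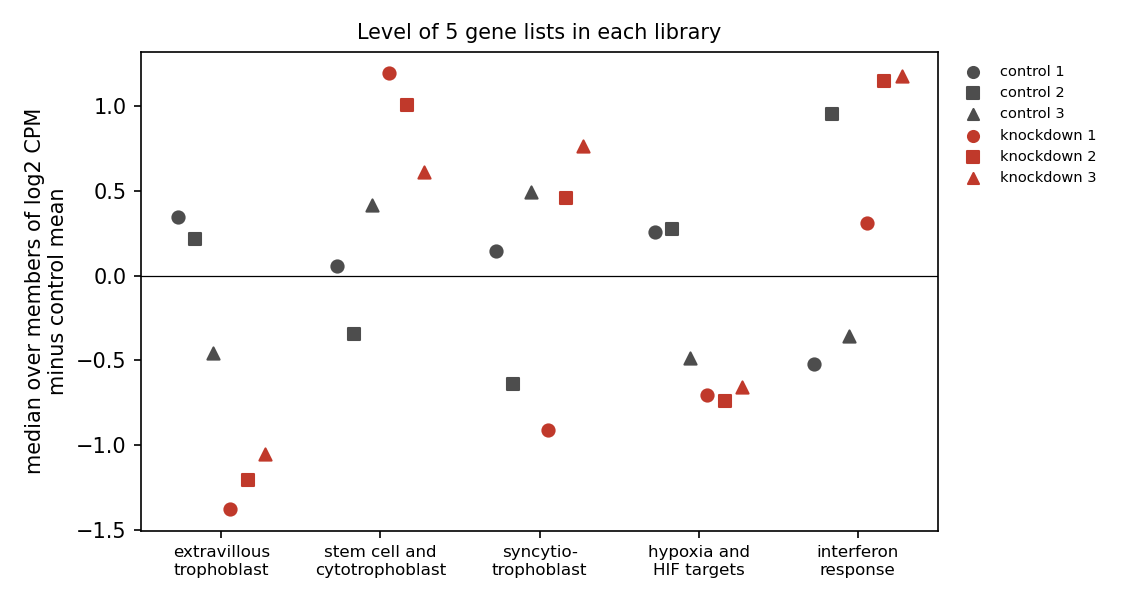
Median over the members of 5 gene lists of the log2 CPM minus the control mean, for each library, with controls in grey, knockdown in red and marker shapes for replicates 1 to 3. The extravillous list lay at -0.45 in control replicate 3 and between -1.38 and -1.05 in the knockdown libraries, and the interferon list lay at 0.96 in control replicate 2, within the range of the knockdown libraries.

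The list of genes induced by hypoxia through HIF transcription factors was lower in the knockdown by camera with the preset correlation (adjusted p = 9.47e-09) and not with an estimated correlation (adjusted p = 0.351). Of 26 measured members, 24 had a negative log2 fold change, with a median of -0.78 (95% bootstrap interval -1.21 to -0.44). None passed over all genes tested in edgeR's quasi-likelihood test, 9 were lower and 0 higher adjusted over the list alone, 17 did not pass, and DESeq2 called 7, all lower. P4HA1, a collagen prolyl hydroxylase gene, fell from 68.2 ± 24.5 to 21.4 ± 7.09 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.00135). The mitophagy gene BNIP3 fell from 80.3 ± 36.7 to 28.5 ± 7.68 CPM (SD, n = 3 each; DESeq2 adjusted p = 0.00794), and the lysyl oxidase gene LOX had 3.55 ± 1.90 CPM in the controls and 0.381 ± 0.296 CPM in the knockdown (SD, n = 3 each). DESeq2 did not call P4HA1 or BNIP3 without control replicate 2, or LOX without control replicate 1. VEGFA and SLC2A1 had log2 fold changes of -0.31 ± 0.30 and -0.11 ± 0.28 (SE) and did not pass. The list median lay at 0.26, 0.28 and -0.49 in control replicates 1 to 3 and between -0.74 and -0.66 in the knockdown libraries.

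The lists of extracellular matrix, epithelial and TGF-beta target genes were higher by camera with the preset correlation, and each held members with a negative log2 fold change. Of 23 matrix and integrin genes, 7 were higher and 2 lower adjusted over the list alone, 14 did not pass, 0 passed over all genes tested, and camera gave an adjusted p of 0.000262, or an adjusted p of 0.327 with an estimated correlation. The basement membrane genes COL17A1 and LAMB3 rose from 10.8 ± 4.79 to 89.5 ± 23.2 CPM and from 8.90 ± 4.77 to 55.7 ± 12.3 CPM (SD, n = 3 each), and thrombospondin 1 (THBS1) rose from 4.82 ± 3.29 to 44.02 ± 11.6 CPM (SD, n = 3 each), with DESeq2 adjusted p-values of 2.22e-11, 7.55e-07 and 3.56e-08. Without control replicate 3 the log2 fold change of THBS1 went from 3.18 to 3.91. The collagen IV gene COL4A1 (-1.18 ± 0.32, SE) and the laminin gene LAMA4 (-1.52 ± 0.43, SE) were lower, with DESeq2 adjusted p-values of 0.00304 and 0.0201. The call of COL4A1 was lost without control replicate 1 and that of LAMA4 without control replicate 1 or 2. The matrix list median went from 0.66 to 0.35 without knockdown replicate 1 (camera adjusted p = 0.0015). Of 20 epithelial genes, 3 were higher over the list alone, 0 lower and 17 did not pass (camera adjusted p = 0.0484, or 0.435 with an estimated correlation). Those 3 were RAB25, ST14 and the tight junction gene CLDN1, with log2 fold changes of 1.83, 1.89 and 3.00, while 5 members had a negative log2 fold change, among them DSP (-0.93), GRHL1 (-0.65) and KRT23 (-0.53). ST14 had 314.5 CPM in knockdown replicate 1 and 110.3 and 100.3 CPM in knockdown replicates 2 and 3, and its log2 fold change was 1.16 without that replicate. That of CLDN1 was 4.61 without control replicate 3 and 2.51 without control replicate 2 or without knockdown replicate 2. The DESeq2 call of CLDN1 was lost in 3 of the 6 DESeq2 fits with 1 library left out. The epithelial list median was 0.80, 0.04 and 0.35 in knockdown replicates 1, 2 and 3 and 0.17, -0.08 and -0.06 in the controls. Camera did not pass for it without knockdown replicate 1 (median 0.19, adjusted p = 0.192) or without control replicate 3 (adjusted p = 0.187). Of 16 TGF-beta targets, 4 were higher, 0 lower and 12 did not pass over the list alone (camera adjusted p = 0.00959, or 0.327 with an estimated correlation). Among them TGFBI had a log2 fold change of 2.49 ± 0.42 (SE) and CYR61 2.94 ± 0.56 (SE; 3.84 without control replicate 3), with DESeq2 adjusted p-values of 3.47e-06 and 1.34e-05.

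Of 11 stromal fibroblast markers, 6 were measured. Adjusted over the list alone 2 were higher, 1 lower and 3 did not pass, and camera gave an adjusted p of 0.00959, or 0.295 with an estimated correlation. COL1A2 rose from 64.5 ± 53.7 to 555 ± 135 CPM and the smooth muscle protein gene TAGLN from 22.9 ± 7.14 to 189 ± 66.6 CPM (SD, n = 3 each), with DESeq2 adjusted p-values of 6.93e-06 and 2.22e-11, while PDGFRA had a log2 fold change of -1.34 ± 0.43 (SE). Leaving out control replicate 3 moved the log2 fold change of COL1A2 from 3.11 to 4.01. Of 7 mesenchymal genes, SNAI2 was higher, S100A4 and TWIST2 were lower and 4 did not pass over the list alone, and the list did not pass (camera adjusted p = 0.784, or 0.806 with an estimated correlation). The log2 fold change of SNAI2 was 3.53, or 5.40 without control replicate 3 and 2.73 without knockdown replicate 2. DESeq2 called SNAI2 and S100A4, calls lost in 3 and 4 of the 6 DESeq2 fits with 1 library left out. It did not call TWIST2 (adjusted p = 0.059), which had 2.33 CPM in the controls and 0.768 CPM in the knockdown. The groups overlapped for S100A4, with 4.39 CPM in control replicate 3 and 5.33 CPM in knockdown replicate 1. The mesenchymal list's median of -0.27 and its mean of 0.03 differed in sign. Of 13 immune cell markers only CD68 and CSF1R were measured, both lower over the list alone with log2 fold changes of -1.56 (-0.93 without control replicate 2) and -0.90 (camera adjusted p = 0.0484, or 0.435 with an estimated correlation), and 14.6% of the reads of CD68 were unique. The immune list did not pass in 4 of the 6 camera tests with 1 library left out.

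**Figure D3:**
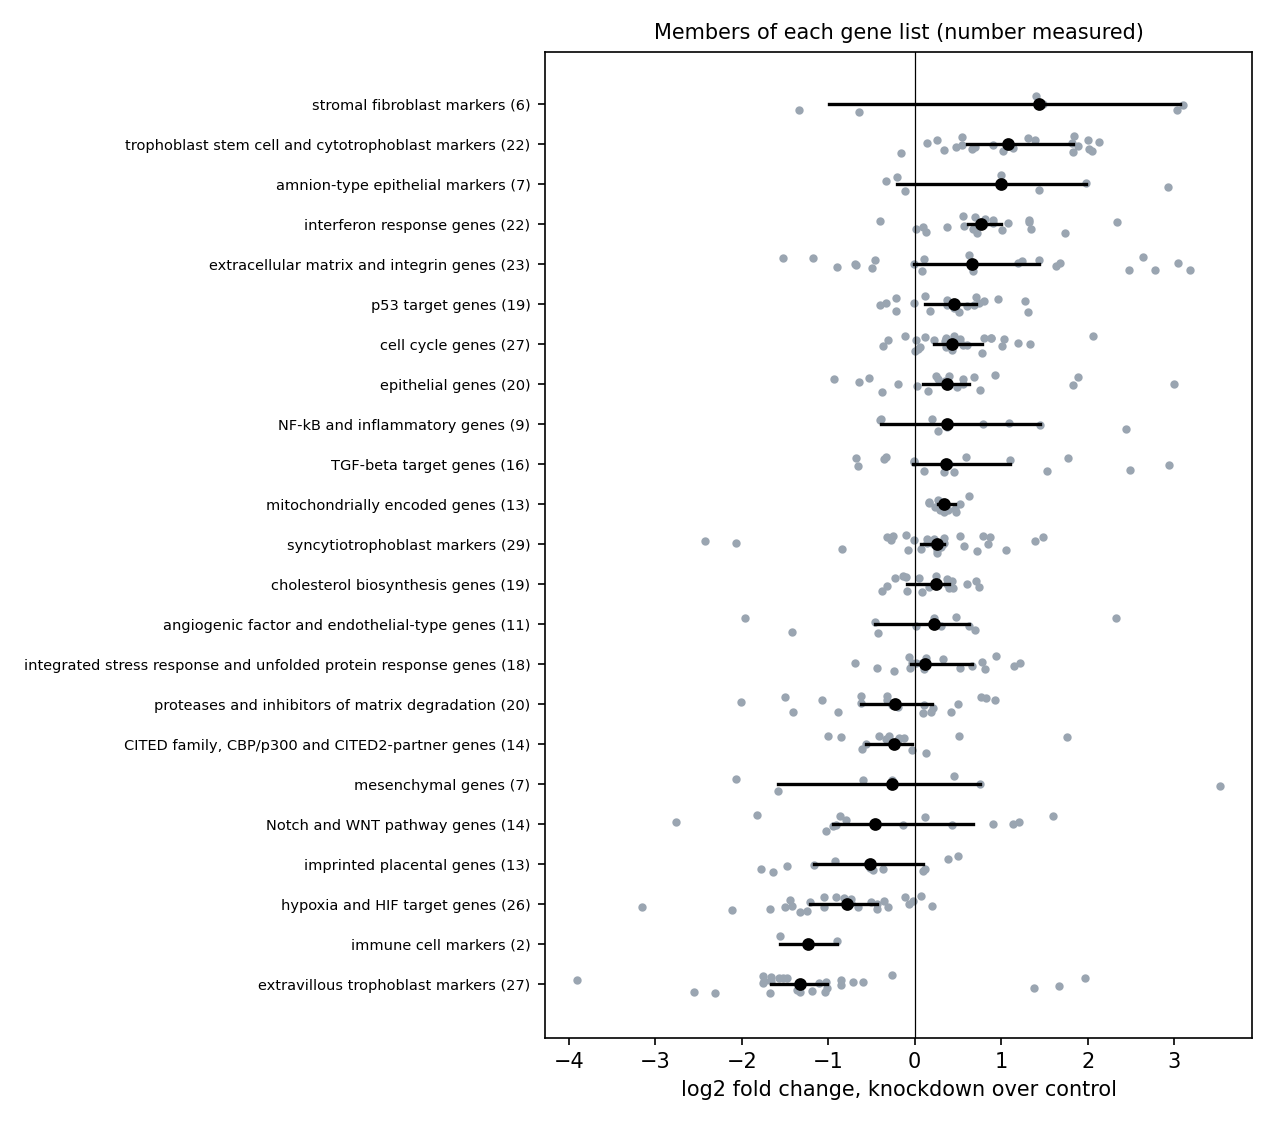
Log2 fold change of knockdown over control for each measured member (grey points) of the 23 gene lists, with the list median (black point) and its 95% bootstrap interval over members (black line). The extravillous list had the lowest median, -1.33, and the stem cell and cytotrophoblast list had a median of 1.08.

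The list of interferon response genes was higher by camera with the preset correlation (adjusted p = 5.65e-06) and not with an estimated correlation (adjusted p = 0.435). Of 22 measured members 21 were positive, with a median of 0.77 (95% bootstrap interval 0.62 to 1.0). Over the list alone 2 members, MX1 and RSAD2, were higher, 0 lower and 20 did not pass, and 0 passed over all genes tested. MX1 rose from 317 ± 90.3 to 804 ± 160 CPM and RSAD2 from 11.6 ± 7.28 to 58.6 ± 27.5 CPM (SD, n = 3 each), with DESeq2 adjusted p-values of 0.00201 and 0.00131. The RSAD2 log2 fold change went from 2.34 to 2.95 without control replicate 2. The call of MX1 was lost without control replicate 1 or without knockdown replicate 3. The controls were not alike, with list medians of -0.52, 0.96 and -0.36 in control replicates 1, 2 and 3 against 0.31, 1.15 and 1.18 in the knockdown replicates, and without control replicate 2 the median log2 fold change was 1.32.

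Imprinted placental genes were lower as a list (13 measured, median -0.51, camera adjusted p = 0.00584, or 0.295 with an estimated correlation), although no member passed over all genes or over the list alone. The imprinted non-coding RNA H19 took 8.18%, 7.60% and 3.92% of the exon reads in control replicates 1, 2 and 3 and 2.15%, 1.84% and 2.08% in the knockdown replicates (DESeq2 adjusted p = 0.000598). The growth factor gene IGF2 and DLX5 had log2 fold changes of -1.64 ± 0.55 and -1.16 ± 0.30 (SE), with DESeq2 adjusted p-values of 0.0269 and 0.0272. IGF2 overlaps the annotated genes INS-IGF2 and IGF2-AS, and 59.1% of its reads were unique. The fold of IGF2 was -1.09 without control replicate 1, and with 1 library left out the call of IGF2 was lost in 2 and that of DLX5 in 5 of the 6 DESeq2 fits. Cell cycle genes were higher by camera (27 measured, median 0.43, adjusted p = 0.0178, or 0.607 with an estimated correlation), with 0 members passing over the list alone. Their list median was 0.86 in knockdown replicate 1 and 0.07 and 0.08 in the other knockdown replicates, and camera did not pass without that replicate (adjusted p = 0.725) or without control replicate 3 (adjusted p = 0.13). The p53 targets (19 measured, median 0.46) gave a camera adjusted p of 0.0484, or 0.435 with an estimated correlation, and 0 members passed over the list alone. The p53 median was 0.23 without knockdown replicate 1 (camera adjusted p = 0.154), and the list did not pass in 4 of the 6 camera tests with 1 library left out.

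The remaining lists did not pass in camera with all 6 libraries. The stress response list of 18 genes had a median of 0.12 (camera adjusted p = 0.136), with ASNS and TRIB3 called higher by DESeq2 (adjusted p = 0.011 and 0.0369), calls lost in 4 and 3 of the 6 DESeq2 fits with 1 library left out. The 14 Notch and WNT pathway genes had a median of -0.46 (camera adjusted p = 0.177), with DLL4 and TCF7L2 lower over the list alone. RNF43 passed as higher over the list alone, but 41.1% of its reads were unique and its level is uncertain. The 9 NF-kB and inflammatory genes (median 0.37), the 13 mitochondrially encoded genes (0.34), the 19 cholesterol synthesis genes (0.25) and the 20 proteases and inhibitors (-0.23) had no member passing over the list alone, with camera adjusted p-values of 0.193, 0.193, 0.204 and 0.305. In the protease list DESeq2 called MMP11 and ADAM12 lower (adjusted p = 0.0125 and 0.0494). Each of these calls was lost in 2 of the 6 DESeq2 fits with 1 library left out. With 1 library left out camera at the preset correlation passed for the stress response list without knockdown replicate 1 (adjusted p = 0.0116), the Notch and WNT list without control replicate 3 (0.0185) and the NF-kB list without knockdown replicate 3 (0.0257). It passed for the cholesterol list without control replicate 3 (adjusted p = 0.0423) or knockdown replicate 1 (0.0215), and for the mitochondrial list without control replicate 3 (0.00323) or knockdown replicate 2 (0.0104). With all 6 libraries and an estimated correlation, camera gave these lists adjusted p-values between 0.531 and 0.783. The mitochondrial genes took 2.12%, 1.87% and 5.10% of the exon reads in control replicates 1, 2 and 3 and 6.11%, 2.38% and 3.05% in the knockdown replicates. The 14 CITED family and partner genes had a median of -0.24 (camera adjusted p = 0.204), and CITED4 had a log2 fold change of 1.77 ± 0.54 (SE; DESeq2 adjusted p = 0.0277). CITED4 had 51.0 CPM in knockdown replicate 1 and 14.3 and 12.6 CPM in knockdown replicates 2 and 3. Without knockdown replicate 1 its log2 fold change was 0.82, and the call was lost in 4 of the 6 DESeq2 fits with 1 library left out. Of 11 angiogenic and endothelial-type genes, EFNA1 was lower over the list alone (-1.96 ± 0.45, SE), with a camera adjusted p of 0.951 and a median of 0.22 in the direction opposite to that of the test. DESeq2 called EFNA1 lower (adjusted p = 0.00202) and NRP2 higher (adjusted p = 0.0123). The log2 fold change of NRP2 was 2.33, or 1.49 without knockdown replicate 1. The calls of EFNA1 and NRP2 were lost in 1 and 3 of the 6 DESeq2 fits with 1 library left out.

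The authors' deposited table gave a false discovery rate under 0.05 to 67 genes outside the Y chromosome, 45 higher and 22 lower in the knockdown, and under 0.01 to 45 genes. All 67 genes of the authors' deposited table had the same direction here, and DESeq2 called 65 of them. Both comparisons come from the same libraries, so the shared direction is no independent check. For CITED2 the authors' deposited table listed a fold change of -5.09 and a false discovery rate of 2.55e-05, and for FLT4 a fold change of -14.4 and a false discovery rate of 6.59e-06, where a negative sign marks lower levels in the knockdown. The lowest false discovery rate in the authors' deposited table, 3.53e-11, belonged to the folate receptor gene FOLR1, which was named after its values were seen and had a fold change of 3.19.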

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

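Intron reads, which no comparison above used, held 1 gene whose signal rose above the controls past the threshold. Over 10501 genes with enough intron reads, the edgeR quasi-likelihood test called 2 genes, of which JPH2 was the one with more intron reads in the knockdown. JPH2 intron reads were 13.5 ± 1.33 intron CPM in the controls and 103 ± 14.5 intron CPM in the knockdown (SD, n = 3 each), a log2 fold change of 2.92 ± 0.36 (SE; edgeR quasi-likelihood adjusted p = 0.0179). The exon reads of JPH2 had a log2 fold change of 3.52. Another annotated gene, ENSG00000287570, overlaps JPH2, and the use of strand in counting is not given. Whether these intron reads come from JPH2 alone was not tested. The other called gene, FLT4, had fewer intron reads in the knockdown, with a log2 fold change of -3.42 ± 0.48 (SE; edgeR quasi-likelihood adjusted p = 0.0328). At an unadjusted p under 0.05, 1061 genes differed on intron reads.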

How the results depend on the processing

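The edgeR exact test, the legacy quasi-likelihood test and DESeq2 with a library left out were chosen after seeing the data. The count of 0 changed genes in edgeR's quasi-likelihood test stayed 0 with RLE factors, library size alone, both limma-trend fits, the legacy test, an adjusted p under 0.01 and a minimum log2 fold change of 1. It became 84 (63 higher, 21 lower) without the filter, 2 (1 higher, 1 lower) on unique reads, 749 (450 higher, 299 lower) in DESeq2 and 644 (386 higher, 258 lower) in the exact test. The cause was not tested. With 1 library left out, the edgeR count ran from 0 to 107 and the DESeq2 count from 248 to 1048, with 0 to 640 higher and 0 to 476 lower over both tools. CITED2 kept its direction in all settings. Its decrease passed the threshold without the filter (log2 fold change -2.35, adjusted p = 0.0388), in DESeq2 (-2.36) and in the edgeR exact test (-2.35), and with 1 library left out its log2 fold change ran from -2.69 to -2.12. The authors' 67 genes became 45 at a false discovery rate of 0.01.

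Of 23 lists, 12 passed in camera, 7 with limma-trend on log2(RPKM + 0.1), 0 with an estimated correlation, 0 in the directional test of fry (8 in its mixed test, which ignores direction), and 10 to 14 with 1 library left out. With an estimated correlation the adjusted p was 0.295 for the extravillous and the stem cell lists, 0.351 for hypoxia and 0.435 for interferon. In fry it was 0.0983 for the extravillous and the stem cell lists, 0.140 for hypoxia and 0.255 for interferon. The estimated correlations, 0.24, 0.23, 0.40 and 0.70 for these lists in that order, exceed the preset 0.01. With 1 library left out, camera gave 1.3e-22 to 3.23e-09 for the extravillous, 1.28e-10 to 2.01e-07 for the stem cell, 7.33e-15 to 9.82e-06 for the hypoxia and 1.5e-23 to 0.00499 for the interferon list. The syncytiotrophoblast list turned lower without control replicate 2 (adjusted p = 0.260), knockdown replicate 2 (0.866) or knockdown replicate 3 (0.208), and passed as higher without knockdown replicate 1 (0.00227). Lists that did not pass with all libraries changed direction, namely the mesenchymal list without the filter (0.882) and without control replicate 1 (0.9999), the mitochondrial list without knockdown replicate 1 (0.457), and the angiogenic list in DESeq2 (0.972), with the replicate block (0.924), in fry (0.999) and without control replicate 1 (0.851), knockdown replicate 1 (0.977) or knockdown replicate 2 (0.866). With 1 library left out, camera gave 0.447 to 0.9999 for the mesenchymal, 0.447 to 0.977 for the angiogenic and 0.00323 to 0.871 for the mitochondrial list. The cause was not tested.

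Of 87 named genes, 61 passed in DESeq2 that did not pass in edgeR's quasi-likelihood test, and 2 changed sign, both without knockdown replicate 1, MT-ND3 (-0.35, or -0.36 in DESeq2, against a highest value of 0.93 with another library left out) and MT-CO2 (-0.20, or -0.21 in DESeq2, against 0.86). These genes had been chosen by DESeq2 calls or by small p-values within their list, so passing and keeping sign were partly fixed by the choice. Libraries with the same replicate number had deviations from their group means that correlated across genes at 0.44, 0.06 and 0.10, and 2 of 3 knockdown libraries correlated best with their own number. With the replicate block the count of changed genes was 0 (0 higher, 0 lower), the CITED2 log2 fold change was -2.24 (adjusted p = 0.0523) and 11 lists passed. Depth limits the genes named with few reads, such as DPPA3 at 0.174 CPM and LOX at 0.381 CPM in the knockdown.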

Other observations

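The tests of explanations in this part were chosen after the results were seen, except the counts over splits of the samples, which were set beforehand. A group of genes that anchors epithelial cells to the basement membrane was put together after the values were seen, from laminin-332, its integrins and the hemidesmosome. Of its 10 genes, 8 had a positive log2 fold change with a median of 1.43, and DESeq2 called 6 of them higher. Of those 6, COL17A1 and LAMB3 stayed called with each library left out, while LAMA3 was lost in 4, LAMC2 and ITGB4 in 2 each and ITGA3 in 1 of the 6 DESeq2 fits. The 3 chains of laminin-332, LAMA3, LAMB3 and LAMC2, had log2 fold changes of 2.48 ± 0.80, 2.64 ± 0.41 and 1.24 ± 0.26 (SE). That of LAMA3 was 3.77 without control replicate 3 and 1.93 without knockdown replicate 2. Its groups overlapped, with 4.28 CPM in control replicate 3 and 3.91 CPM in knockdown replicate 1. COL17A1 had 3.05 ± 0.37 (SE) and ITGA3 had 1.63 ± 0.38 (SE), or 1.06 without knockdown replicate 1. The members that stood in no fixed list, PLEC, CD151 and DST, had log2 fold changes of 0.75, -0.27 and -0.37, a median of -0.27, and are too few to say whether the structure as a whole may be involved.

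All 8 measured metallothionein genes, which encode metal-binding proteins, had a positive log2 fold change, between 0.88 (MT1E) and 3.73 (MT2A, 2.17 without knockdown replicate 1). Their median relative to the control mean was 2.25 in knockdown replicate 1, 0.42 and 0.74 in knockdown replicates 2 and 3, and between -0.12 and 0.21 in the controls. Without MT2A, which drew attention to the family, camera gave p = 0.190 with an estimated correlation of 0.92 between members, so a rise of the family may or may not be present. Across 9448 genes, which are not independent replicates, the log2 fold changes on intron and exon reads had r = 0.76, and of the 427 DESeq2-called genes with enough intron reads, 416 (97.4%) had the same sign on both, which any difference between these libraries would give, since both kinds of reads come from them and the genes were chosen on exon reads.

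The first pattern is the lower extravillous and higher stem cell and cytotrophoblast lists. A scaling error from a few abundant genes such as H19 would shift both lists alike and cannot alter the gap between their medians. That gap was -2.41 (95% bootstrap interval -3.20 to -1.74). It restates the pattern and is no separate test of it. Knockdown replicate 1 alone does not account for it, since without that library the extravillous median was -1.10 (camera adjusted p = 3.23e-09 with the preset correlation, where all libraries together gave an adjusted p of 0.295 with an estimated correlation). A change in cell shares was examined in 1 form only, a lower share of extravillous cells that raises the markers of all other cell types alike. Other changes in cell shares were not tested. The examined form stays open. The stem cell median exceeded the syncytiotrophoblast median by 0.82 with all libraries (permutation test over members, p = 0.0002) but by 0.26 without knockdown replicate 1. That p-value and the bootstrap interval above take members as independent and measure no spread between samples. The members move together, with estimated correlations of 0.23 in the stem cell and 0.56 in the syncytiotrophoblast list. Incomplete differentiation after loss of CITED2 may equally give this pattern, and bulk RNA does not separate it from a change in cell shares.

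The second pattern is the lower hypoxia list. CITED2 is known to compete with HIF for CBP and p300, and release of HIF from that competition would raise HIF targets, while the list median was -0.78. No verdict on that mechanism follows, since it would not lower the list and the spread of the median rests on members that move together (estimated correlation 0.40). A single library does not account for it in camera with the preset correlation, where the highest adjusted p with 1 library left out was 9.82e-06. What lowers these genes stays open, including culture density or oxygen, for which the labels give no values, and the list did not pass with an estimated correlation (adjusted p = 0.351).

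The third pattern is that CITED2 exon reads were lower in all 3 knockdown libraries. Its intron reads numbered 403, 501 and 229 in the controls and 90, 125 and 100 in the knockdown libraries, a log2 fold change of -2.09 ± 0.50 (SE), and the exact permutation test gave p = 0.1, the smallest possible. Loss of spliced RNA alone, the textbook action of an shRNA in the cytoplasm, would leave intron reads near the control level if they came from unspliced RNA. Under that condition, which was not tested, these values argue against loss of spliced RNA as the whole cause. Intron reads were 2.95%, 3.35% and 3.62% of the reads of CITED2 in control replicates 1 to 3. In knockdown replicates 1 to 3 they were 3.87%, 4.28% and 4.30%. A general loss of intron reads is also not seen, as the share of intron reads in the knockdown libraries was 0.939 times that in the controls (3.90% ± 0.56 against 4.15% ± 1.67, SD, n = 3 each). A candidate explanation is lower transcription of CITED2 in these cells, and cleavage of unspliced transcripts in the nucleus or reads from the antisense gene that spans CITED2 also remain open.

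The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In edgeR's quasi-likelihood test the real split and the highest other gave 0 genes, and a count of 0 is reached by all 10 splits whatever the data, so that comparison shows nothing. At an unadjusted p under 0.05 the real split gave 2065 genes in that test, fewer than other splits with 2296 and 2708. In DESeq2 the real split gave 749 genes and 3 of the 10 splits gave as many, the highest other being 864. The split with 864 genes set control replicates 1 and 2 with knockdown replicate 1 against the rest. The second principal component of log2 CPM, an axis of variation among libraries, separated the same sets. Its scores were 41.7, 33.0 and 52.9 against -33.7, -61.5 and -32.4. It held 35.9% of the variance, against 42.7% for the first component. In camera 12 lists passed for the real split and 2 of the 10 splits gave as many, the highest other being 14. For the split that sets control replicates 1 and 2 with knockdown replicate 3 against the rest, camera gave the extravillous list an adjusted p of 3.25e-15, against 8.17e-15 for the real split. Across genes the log2 CPM of control replicate 3 correlated with that of knockdown replicate 2 at 0.972 and with that of control replicate 1 at 0.960.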
